A study of Mus musculus with 6 samples.

How the data were processed

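Poly-A RNA was sequenced from the hearts of 6 C57BL/6J mice aged 8 to 10 weeks, 7 days after myocardial infarction by ligation of the left anterior descending coronary artery. Per the labels' protocols, RNA came from ventricular tissue below the ligature, and a tamoxifen diet was given from surgery until collection. All mice carried Postn-CreER, a tamoxifen-inducible recombinase under the promoter of periostin, a gene of activated fibroblasts. The control group (CTL, n = 3) had wild-type Runx1, and the knockout group (Runx1_FB_KO, n = 3) had the conditional Runx1 allele. CTL replicate 1 was female and CTL replicates 2 and 3 were male. Runx1_FB_KO replicate 1 was male and Runx1_FB_KO replicates 2 and 3 were female. Groups, replicate numbers and sex were taken from the labels.

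The authors deposited 1 transcript table per sample, with estimated counts, TPM and effective length for each of 116546 transcripts. Per the submitters' processing notes, the tools were Salmon 1.5.2 and DESeq2 1.44.0 and the genome build was mm10 (GRCm38). The transcript annotation release was not given in the sources used here. The deposited estimated counts need not be whole, because Salmon divides reads between transcripts that share sequence. The deposited TPM values sum to the same total in each sample and were used only for Runx1 transcripts and to weight effective lengths, another column that the authors deposited.

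Transcripts were matched to genes by identifier without version, with GENCODE M21 (GRCm38). In all, 115977 transcripts matched and 569 did not. The unmatched transcripts held 0.078% to 0.102% of a sample's reads and were left out. Estimated counts were summed over 35498 genes and rounded to whole numbers. The totals ran from 16598561 to 19987279 estimated reads per library. Genes were filtered with filterByExpr, which left 14237, and libraries were scaled by TMM. The TMM factors ran from 0.732 to 1.214. Knockout was compared with CTL by edgeR 4.0.16 quasi-likelihood tests on genotype alone, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors were computed as the absolute log2 fold change divided by the square root of F.

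Before the data were examined, 41 gene lists were fixed, covering fibrosis, heart muscle, metabolism, inflammation, RNA quality and the cell types that infarcted ventricle could hold. Older symbols were replaced for 3 members. Some genes belong to more than a single list, so the lists are not independent of each other. Lists with at least 5 tested members were compared with the other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and a variance trend, adjusted over the lists. A list score is the mean log2 CPM of its members minus the mean of the 3 CTL libraries. The rule for named genes was also fixed before the data were examined. It takes Runx1, then up to 12 genes in each direction that pass, have a mean log2 CPM of at least 0, separate the groups and keep their direction with sex as a covariate. Where no gene passes it takes the 5 with the smallest p in each direction, named as not passing. It adds the 3 members with the smallest p of each called list and the 2 members with the smallest p of each fibrosis, cardiac or target list that was not called. Predicted genes, pseudogenes, antigen receptor segments and sex-linked genes used to check labels were left out of the part that is not tied to a list. A gene that the rule names is not reported here, and no other took its place, which left 73 named genes.

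The alternatives were sex as a covariate, the replicate number as a block, other scalings (RLE size factors, upper quartile, library size alone), no filter, a filter of CPM of at least 1 in 3 samples, an offset for effective length, protein-coding genes only, and omission of mitochondrially encoded genes and globins. Each library was left out in turn, and the cardiomyocyte score was tried as a covariate. Other tests were DESeq2 1.42.0, limma-voom, glmTreat against a fold change of 1.2, a threshold of 0.1, camera with an estimated correlation, camera on voom weights, and fry. Further fits were chosen after seeing the data: voom with sample quality weights, DESeq2 on the genes that filterByExpr kept (its other fit had no such filter), and camera with an estimated correlation either with sex as a covariate or without Runx1_FB_KO replicate 3.

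The gene and list tests were checked on simulated data for the knockout against CTL comparison, with counts drawn for 14237 genes. Of these, 200 were changed to test recovery, and a further set, raised by 1 on the log2 scale, formed a shifted list. With the spread of all 6 libraries, 7.5% of genes changed by 1 on the log2 scale were recovered, 65.7% of those changed by 2 and 83.3% of those changed by 3. With the spread estimated without Runx1_FB_KO replicate 3, the shares were 68.7%, 88.1% and 95.5%. Of the unchanged genes, 6 were called with the first spread and 15 with the other. A shifted list was found both times, and 1 of the 41 other lists was also called both times. Counts were drawn independently for each gene and library. The simulation thus holds no correlation between genes, on which the list test depends. It also holds no library that differs over many genes at once, as Runx1_FB_KO replicate 3 did. Its shares and counts are therefore not the power or error rates of the real comparison. Sex labels were checked against 4 Y-linked genes, and other sex-linked genes were not used here. No pair of libraries agreed within sampling noise, with a chi-square of at least 23.2 per gene. Analyses used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, with BLAST 2.17.0 for 1 sequence comparison.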

Results

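Hearts were profiled 7 days after myocardial infarction, by poly-A RNA sequencing of ventricular tissue below the ligature, to ask how loss of Runx1 in periostin-expressing cells affects the infarcted heart. Runx1 encodes a DNA-binding transcription factor. The CTL group (n = 3) was compared with the Runx1_FB_KO group (n = 3), both on tamoxifen and both carrying the recombinase. The libraries held 16598561 to 19987279 estimated reads. Mitochondrially encoded genes took 5.69%, 7.11% and 5.36% of the reads in CTL replicates 1, 2 and 3, and 24.49%, 19.61% and 10.37% in Runx1_FB_KO replicates 1, 2 and 3. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in each of the 3 libraries labelled female and at least 339 reads in each of the 3 labelled male.

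The targeted gene was lower in the knockout libraries, but not past the threshold. Runx1 (ENSMUSG00000022952, GRCm38 chromosome 16, 92601466 to 92826149, minus strand) was at 89.6 ± 5.89 CPM in CTL (SD, n = 3) and 31.9 ± 30.9 CPM in Runx1_FB_KO (SD, n = 3). The knockout libraries held 17.5, 10.9 and 67.4 CPM in replicates 1, 2 and 3, all below the lowest CTL library at 85.5 CPM. The log2 fold change was -1.48 (SE 0.63, edgeR adjusted p = 0.154), and with sex as a covariate it was -1.79 (edgeR adjusted p = 0.154). Without Runx1_FB_KO replicate 3 it was -2.61 (SE 0.22, edgeR adjusted p = 0.000142). With the cardiomyocyte score as a covariate its sign turned, to 1.197 (SE 0.36, edgeR adjusted p = 0.846). Without Runx1_FB_KO replicate 2 the log2 fold change was -1.07. The exon removed by the recombinase is not given in the labels, and reads from other exons and from cells without periostin still count. Among the annotated transcripts, ENSMUST00000023673.13 was given the most reads, with 1545.8, 1435.2 and 1244.2 in CTL replicates 1, 2 and 3 and 181.3, 118.2 and 997.4 in the knockout. For ENSMUST00000113956.9 these were 530.3, 474.5 and 380.5 in CTL and 84.8, 18.3 and 309.5 in the knockout. A transcript with few reads, ENSMUST00000168195.7, was given 72.0, 15.4 and 73.2 reads in CTL and 0.0 reads in each knockout library, an allocation between transcripts that share sequence.

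**Figure D1:**
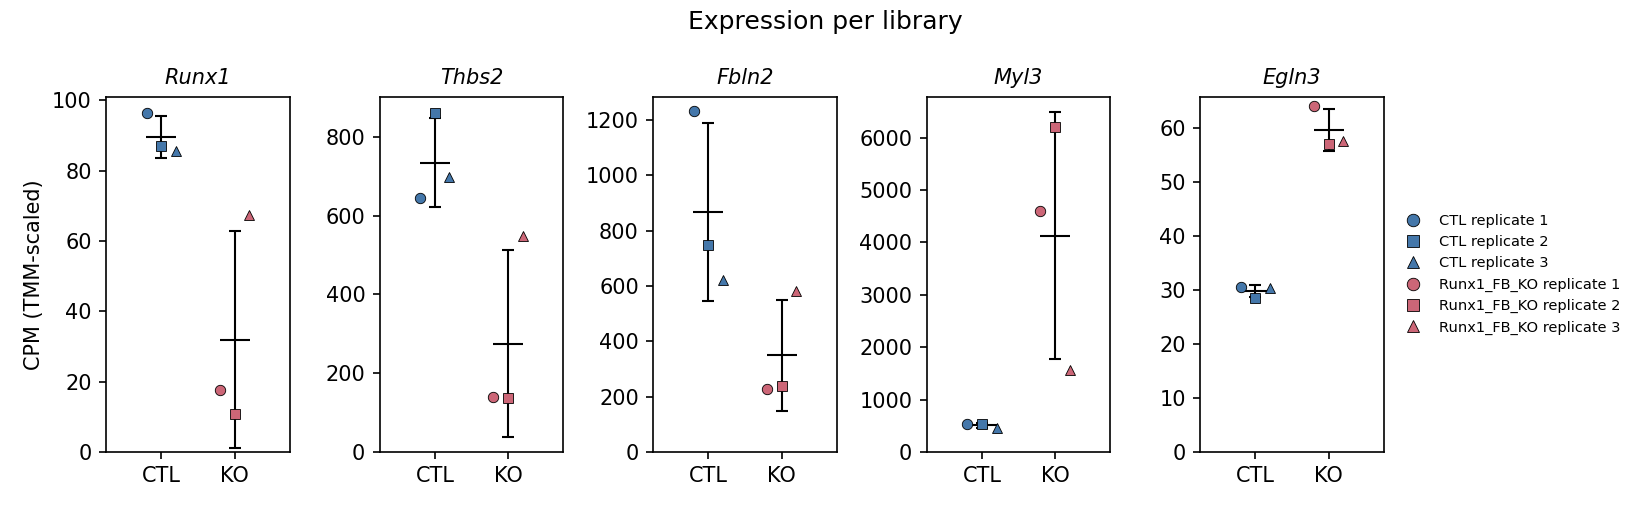
Expression of Runx1, Thbs2, Fbln2, Myl3 and Egln3 in CPM scaled by TMM (y axis, from 0) in CTL and Runx1_FB_KO libraries (KO). Symbols are single libraries, the horizontal mark is the group mean and the bars are the SD (n = 3). Runx1 is at 67.4 CPM in Runx1_FB_KO replicate 3, nearer to CTL than the 17.5 and 10.9 CPM of the other knockout libraries.

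The knockout libraries did not lie equally far from CTL. The first principal component of the 500 most variable genes held 56.5% of the variance and placed CTL at -22.2, -22.9 and -30.0 and Runx1_FB_KO at 38.5, 45.5 and -9.0 for replicates 1, 2 and 3. Runx1_FB_KO replicate 3 correlated with the CTL libraries at 0.956, 0.969 and 0.966 across genes, and with Runx1_FB_KO replicates 1 and 2 at 0.924 and 0.913. Genes are not independent replicates, so these correlations carry no test.

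**Figure D2:**
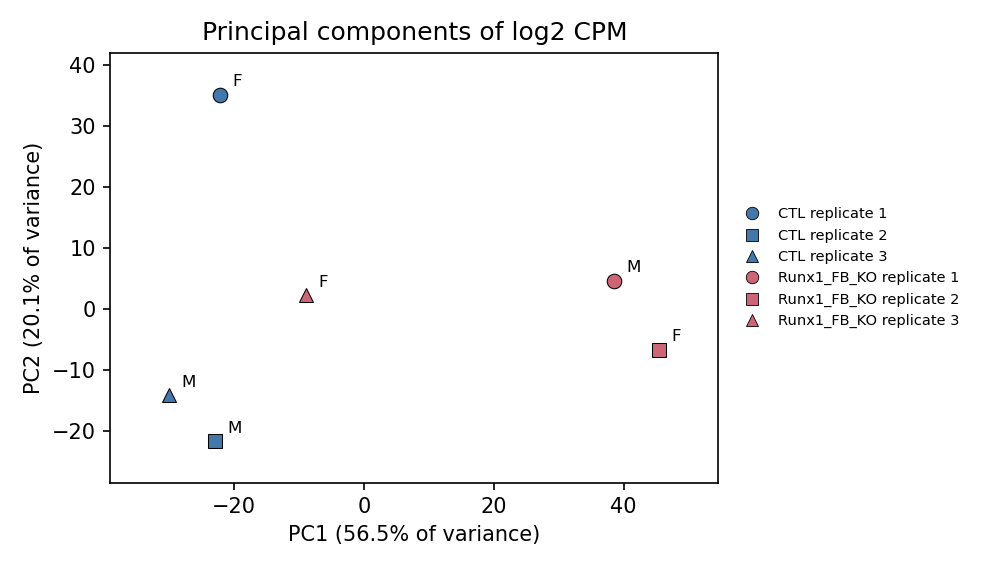
Principal components of log2 CPM over the 500 most variable genes, with component 1 (56.5% of variance) on the x axis and component 2 (20.1%) on the y axis. Each symbol is a library and letters give its sex. Runx1_FB_KO replicate 3 sits at -9.0 on the first component, between the CTL libraries and the other knockout libraries at 38.5 and 45.5.

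No gene passed the threshold when all 6 libraries were tested. Of 14237 genes, 0 had an edgeR adjusted p under 0.05, and the smallest was 0.0682. At an unadjusted p under 0.05 there were 4619 genes, 2752 higher and 1867 lower in the knockout. DESeq2 by default sets aside genes of low mean count before adjustment. Without filterByExpr it gave a p to 20191 genes and called 2824 (2092 higher, 732 lower). On the genes that filterByExpr kept it gave a p to 14227 and called 2995 (2172 higher, 823 lower). On the filtered genes limma-voom called 0, and a threshold of 0.1 in edgeR gave 2311 (1778 higher, 533 lower). Without filterByExpr edgeR called 889 genes. Without Runx1_FB_KO replicate 3 edgeR called 6947 genes, 3662 higher and 3285 lower. In 39.0% of the genes tested, 2871 higher and 2676 lower, all 3 knockout values lay beyond all 3 CTL values. Chance gives 10% on average over splits of the libraries. Genes move together, so a single split can lie far from 10% without an effect of genotype.

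The genes with the smallest p had an edgeR adjusted p of 0.0682 each (0.0979 with sex as a covariate) and are named as not passing. Among those higher in the knockout, Tfrc, the transferrin receptor, was at 22.4 ± 6.08 CPM in CTL and 128 ± 28.4 CPM in the knockout (SD, n = 3). Egln3, a prolyl hydroxylase of the hypoxia response, was at 29.9 ± 1.11 and 59.6 ± 3.87 CPM, and Dusp8, a phosphatase of stress-activated kinases, at 13.5 ± 1.04 and 32.7 ± 3.97 CPM. Frem2, an extracellular matrix protein, had a log2 fold change of 2.68 (SE 0.31), and Pirt, a membrane regulator of ion channels, one of 2.47 (SE 0.31). Among those lower, Crct1 had 47, 36 and 69 reads in CTL replicates 1, 2 and 3 and 0, 0 and 1 reads in the knockout. The leukocyte integrin gene Itgal was at 12.02 ± 1.27 CPM in CTL and 4.26 ± 1.14 CPM in the knockout. Wfdc17 was at 52.3 ± 6.32 and 20.4 ± 6.08 CPM, Mid1 at 30.2 ± 0.59 and 14.9 ± 2.35 CPM, and Tmem203 at 11.5 ± 1.69 and 4.76 ± 0.81 CPM.

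Genes of heart muscle and of its oxidative metabolism were higher as groups in the knockout. The cardiomyocyte list (median log2 fold change 2.30, camera adjusted p = 4.58e-12), oxidative phosphorylation (2, 6.93e-15), fatty acid oxidation (2.46, 5.91e-12), calcium handling and excitation (1.54, 7.31e-09) and the mitochondrially encoded genes (2.08, 6.98e-05) rose by camera. With an estimated correlation each had an adjusted p = 0.618. All 24 cardiomyocyte genes, 32 oxidative phosphorylation genes, 24 fatty acid oxidation genes and 13 mitochondrially encoded genes passed when adjusted over the list alone, as did 20 of the 23 calcium handling genes, and 0 of any list passed over all genes tested. Myl3, a ventricular myosin light chain, was at 505 ± 41.6 CPM in CTL and 4128 ± 2357 CPM in the knockout, and the mitochondrial creatine kinase Ckmt2 at 191 ± 36.6 and 1584 ± 902 CPM. The cytochrome oxidase subunits Cox6a2 and Cox7a1 had log2 fold changes of 2.93 (SE 0.54) and 3.26 (SE 0.56), and Cycs (cytochrome c) and Ndufb5 (complex I) had 2.08 and 1.99. For fatty acid handling, Fabp3 was at 331 ± 50.7 and 1830 ± 920 CPM, and Cpt1b, which loads fatty acids for import into mitochondria, and Etfdh had log2 fold changes of 2.73 and 2.56. The potassium channel genes Kcnip2 and Kcnq1 and the calcium-binding gene Hrc had 3.99, 1.43 and 3.96, and mt-Nd3, mt-Atp8 and mt-Nd4l had 2.34, 2.002 and 2.04. The cardiomyocyte score was 2.47, 2.79 and 1.14 in Runx1_FB_KO replicates 1, 2 and 3, against an SD of 0.19 in CTL. The same libraries held 24.49%, 19.61% and 10.37% mitochondrial reads. With the cardiomyocyte score as a covariate, the oxidative phosphorylation and fatty acid oxidation lists turned to lower (adjusted p = 5.3e-07 and 2.17e-09), and the mitochondrially encoded call was lost (0.904). The calcium handling list lost its call and turned direction (0.67). That list shares Ryr2, Atp2a2, Pln and Slc8a1 with the cardiomyocyte list, and the fatty acid oxidation list shares Fabp3 with it.

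Smaller shifts in the same direction were called for the fetal and stress cardiomyocyte list (median log2 fold change 0.50, camera adjusted p = 0.0239) and the glycolysis and hypoxia list (0.41, 0.0317), each with adjusted p = 0.618 with an estimated correlation. Adjusted over the list alone, 2 of 16 fetal and stress genes were higher, and 6 of 22 glycolysis and hypoxia genes were higher and 1 lower. Over all genes tested 0 passed. Nrap and Xirp1, proteins of the muscle attachment apparatus, had log2 fold changes of 1.61 and 1.25, and Myh7, the slow myosin heavy chain, was at 614 ± 256 CPM in CTL and 1850 ± 764 CPM in the knockout. Vegfa, a growth factor for vessels, and Hk2 (hexokinase) had 1.71 (SE 0.26) and 1.81 (SE 0.35). The fetal and stress call was lost without CTL replicate 1 (adjusted p = 0.0531) and without Runx1_FB_KO replicate 3 (0.147). The glycolysis and hypoxia call was lost without CTL replicate 2 (0.133), without Runx1_FB_KO replicate 3 (0.104, with a list median of 0.64) and with sex as a covariate (0.14). Under library size alone the list median was -0.09, where the median of all genes was -0.52 and that of the fetal and stress list was 0.04. The knockout libraries held 24.49%, 19.61% and 10.37% mitochondrial reads. With the cardiomyocyte score as a covariate, these were the 2 called lists that kept call and direction. The fetal and stress scores were 0.22, 0.36 and 0.69 in Runx1_FB_KO replicates 1, 2 and 3 (CTL -0.22 to 0.21). They were highest in replicate 3, which had the lowest cardiomyocyte score of the knockout libraries.

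Genes of activated fibroblasts and of the scar matrix were lower as groups. By camera the myofibroblast and activated fibroblast list (median log2 fold change -1.30, adjusted p = 1.3e-05), fibrillar and structural matrix (-1.15, 2.7e-05), collagen processing and crosslinking (-0.96, 3.85e-05), TGF-beta signalling (-0.45, 0.00528) and the osteochondral and matrifibrocyte list (-0.91, 0.00905) fell. With an estimated correlation each had an adjusted p = 0.618. All 24 myofibroblast genes, 26 matrix genes and 21 collagen processing genes had negative log2 fold changes, yet 0 of them passed either adjusted over the list alone or over all genes tested. All knockout values lay below all CTL values for only 3 of these myofibroblast genes (Fap, Thbs2 and Myl9), 10 matrix genes and 10 collagen processing genes. Fap, a surface protease of activated fibroblasts, was at 28.0 ± 1.66 CPM in CTL and 14.9 ± 8.38 CPM in the knockout, and the matricellular gene Thbs2 at 735 ± 113 and 275 ± 237 CPM. Myl9, a contractile light chain, and Fbln2, a matrix glycoprotein, had log2 fold changes of -1.38 (SE 0.56) and -1.31 (SE 0.46), and the collagens Col18a1 and Col5a1 had -1.23 and -1.27. Crtap, Bmp1 and Fkbp10, which modify or process procollagen, had -1.02, -1.07 and -1.35. In the TGF-beta signalling list Ski, Tgfbi and Tgfb1 had -0.47, -1.35 and -0.88, and the groups overlapped for Tgfbi and Tgfb1. That list also holds inhibitors of the pathway, such as Ski and Bambi, so its fall is not a measure of signalling. In the osteochondral list Alpl, which encodes alkaline phosphatase, went the other way (1.17, SE 0.18, the only member past the threshold adjusted over the list alone), while Prg4 and Runx2 had -0.70 and -1.28. The myofibroblast score was -2.21 and -2.69 in Runx1_FB_KO replicates 1 and 2 and -0.11 in replicate 3, within the CTL range of -0.14 to 0.10. The same 3 libraries held 24.49%, 19.61% and 10.37% mitochondrial reads. Runx1_FB_KO replicate 3 also lay within CTL for the matrix score (-0.08, CTL -0.14 to 0.09) and the osteochondral score (0, CTL -0.63 to 0.49). Its collagen processing score (-0.13, CTL -0.10 to 0.05) and TGF-beta score (-0.07, CTL -0.06 to 0.05) lay just below CTL. The list medians without Runx1_FB_KO replicate 3 were -2.37 for myofibroblast, -1.89 for matrix, -1.65 for collagen processing and -1.87 for osteochondral genes. Without Runx1_FB_KO replicate 2 the myofibroblast and collagen processing medians were -0.84 and -0.64. Without Runx1_FB_KO replicate 3 the log2 fold changes were -1.43 for Fap, -2.37 for Thbs2, -2.34 for Myl9, -2.19 for Col18a1, -2.26 for Col5a1, -1.67 for Bmp1, -2.21 for Fkbp10, -1.35 for Tgfb1 and -1.96 for Runx2. Without CTL replicate 1 Tgfbi had -0.83. With library size alone the TGF-beta median was -0.86, where that of all genes was -0.52. Without Runx1_FB_KO replicate 3, 23 of 24 myofibroblast genes and 25 of 26 matrix genes were lower past the threshold over all genes. The osteochondral call was lost without CTL replicate 2 (adjusted p = 0.0515) and with library size alone (0.289), and with the cardiomyocyte score as a covariate all of these lists turned to higher.

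**Figure D3:**
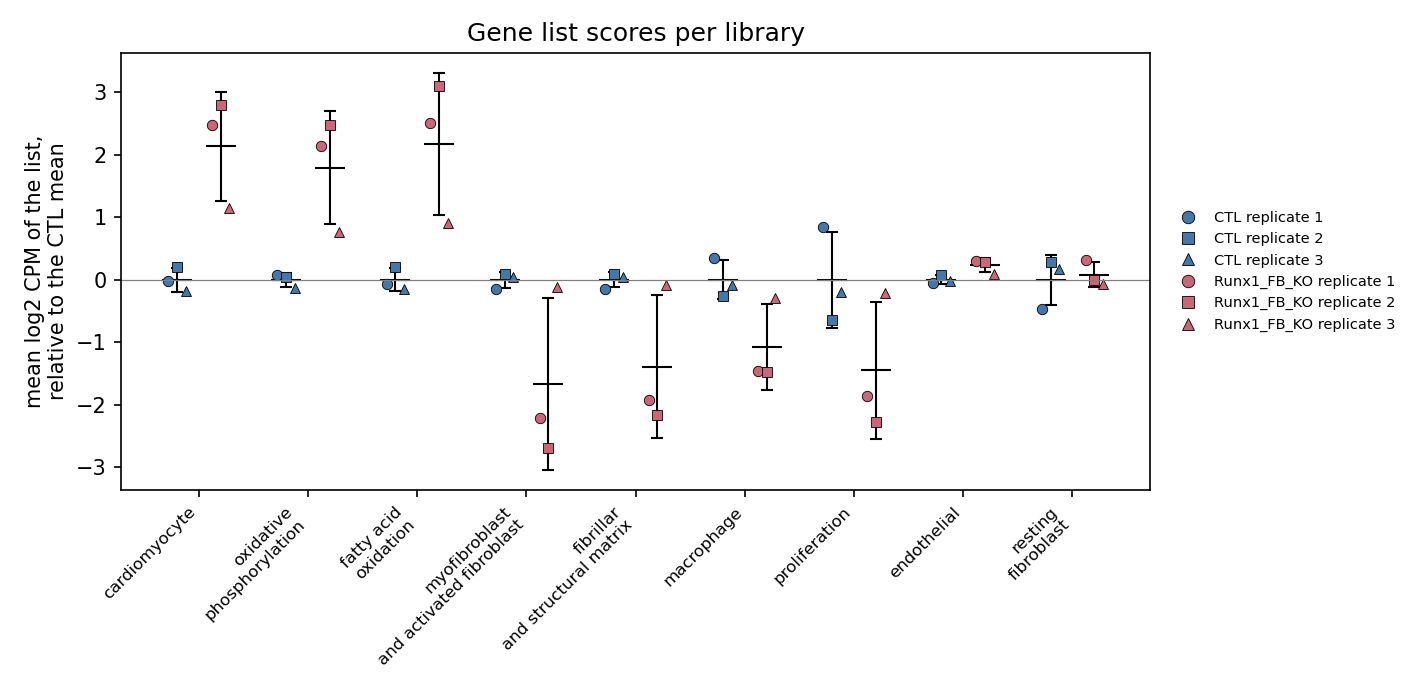
Scores of 9 gene lists per library (y axis, mean log2 CPM of the members relative to the CTL mean) in CTL and Runx1_FB_KO. Symbols are libraries, the horizontal mark is the group mean and bars are the SD (n = 3). The cardiomyocyte scores of the knockout libraries are 2.47, 2.79 and 1.14, while the myofibroblast score of Runx1_FB_KO replicate 3 is -0.11, beside -2.21 and -2.69 in replicates 1 and 2.

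Immune and cell cycle genes were also lower as groups. The macrophage list (median log2 fold change -1.01, camera adjusted p = 2.7e-05), proliferation (-1.42, 8.83e-05), cytokines and chemokines (-0.86, 0.000182), T and NK cell (-1.42, 0.000285), monocyte (-1.15, 0.00604), lipid-associated macrophage (-1.18, 0.0239), interferon response (-0.28, 0.0239) and B and plasma cell (-2.37, 0.031) lists fell, each with adjusted p = 0.618 with an estimated correlation. Adjusted over the list alone 0 members of these lists were lower past the threshold, and 1 was higher, Lpl in the lipid-associated macrophage list. Lpl encodes lipoprotein lipase, which heart muscle also expresses, and was at 1026 ± 244 CPM in CTL and 5134 ± 2478 CPM in the knockout. Over all genes tested 0 passed. Mertk, a receptor for the uptake of dying cells, was at 58.5 ± 16.9 CPM in CTL and 26.5 ± 8.12 CPM in the knockout, and the macrophage gene Aif1 had a log2 fold change of -1.17. Ccr2, the receptor of recruited monocytes, was at 79.8 ± 9.17 and 37.9 ± 17.1 CPM, with F10 and Plac8 at log2 fold changes of -1.51 and -1.19. The monocyte list shares Fn1 and Vcan with the matrix list and Thbs1 with the myofibroblast list, so its fall is not separate from theirs. The cell cycle genes Ccnb2, Aurka and Ccnb1 had -1.83, -1.77 and -1.65, but -1.25, -0.97 and -1.09 without CTL replicate 1 and -2.62, -2.47 and -2.75 without Runx1_FB_KO replicate 3. The inflammatory genes Ccl3, Ccl6 and Nlrp3 had -1.27, -0.61 and -1.11, and the lymphocyte genes Cd3g, Lck and Nkg7 had -2.03, -2.23 and -1.40. These lymphocyte genes were low, with means of 1.92, 3.81 and 2.52 CPM in CTL and 0.47, 0.79 and 0.96 CPM in the knockout. Arg1 and Cd63 had -1.51 and -0.83. The interferon genes Mx1, Bst2 and Zbp1 had -1.14, -0.70 and -0.62, and the B cell genes Pax5, Jchain and Ms4a1 had -3.82, -2.42 and -2.58. The groups overlapped for Ccnb1, Arg1, Cd63, Jchain and Ms4a1. Jchain was at 6.09 CPM in CTL replicate 1, below Runx1_FB_KO replicates 1, 2 and 3 at 9.23, 17.1 and 27.6 CPM. Without CTL replicate 3 Pax5 and Ms4a1 had -2.07 and -1.09, and with sex as a covariate Jchain had -1.04 (edgeR adjusted p = 0.728). Without CTL replicate 1 Arg1 had -0.86. The same knockout libraries held 24.49%, 19.61% and 10.37% mitochondrial reads. With the cardiomyocyte score as a covariate, the macrophage, proliferation and lipid-associated macrophage lists turned to higher (adjusted p = 5.57e-05, 1.74e-06 and 0.00369), and the T and NK cell and B and plasma cell calls were lost (0.301 and 0.983). The monocyte, cytokine and interferon response lists lost their calls and turned direction (0.142, 0.142 and 0.526).

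Runx1_FB_KO replicate 3 lay within the CTL range for several of these lists. Its proliferation score was -0.21 (CTL -0.65 to 0.85), its lipid-associated macrophage score -0.03 (CTL -0.47 to 0.62) and its B and plasma cell score -0.83 (CTL -2.17 to 1.49). Its macrophage score was -0.29, below CTL replicate 2 at -0.26, beside -1.46 and -1.48 in Runx1_FB_KO replicates 1 and 2. Without Runx1_FB_KO replicate 3 the proliferation median was -2.42 and the cytokine and chemokine median -1.37 over the members also tested with all 6 libraries. Without CTL replicate 1 the proliferation and lipid-associated macrophage medians were -0.83 and -0.63, and without CTL replicate 2 the interferon response median was -0.15. With library size alone the interferon response median was -0.73, where that of all genes was -0.52.

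Several of these calls rested on single libraries or on the scaling. The lipid-associated macrophage call was lost without CTL replicate 1 (adjusted p = 0.0669) or Runx1_FB_KO replicate 1 (0.0701), and with library size alone (0.311), which also ended the monocyte call (0.109). The interferon response call was lost without CTL replicate 2 (0.128), without Runx1_FB_KO replicate 2 (0.102) and with sex as a covariate (0.0635). The B and plasma cell call was lost without CTL replicate 2 (0.11), CTL replicate 3 (0.118) or Runx1_FB_KO replicate 3 (0.0573), with sex as a covariate (0.109), library size alone (0.321) or upper quartile scaling (0.0542), with a filter of CPM of at least 1 in 3 samples (0.0808) and on voom weights (0.0677). CTL replicate 1, the only female control, had a B and plasma cell score of -2.17 and a proliferation score of 0.85.

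The remaining 21 lists were not called with all 6 libraries, though some were under other settings. Matrix proteases passed with sex as a covariate (adjusted p = 0.0266), with RLE scaling (0.0458) and without CTL replicate 3 (0.0405) or Runx1_FB_KO replicate 3 (0.0114), but had an adjusted p = 0.618 with an estimated correlation over all 6 libraries. The dendritic cell list passed with RLE scaling (0.0425), no filter (0.031) or a length offset (0.0422), and without CTL replicate 1 (0.00548), CTL replicate 3 (0.0483), Runx1_FB_KO replicate 2 (0.0444) or Runx1_FB_KO replicate 3 (0.031). It too had an adjusted p = 0.618 with an estimated correlation over all 6 libraries. The neutrophil list passed with sex as a covariate (0.00156) and without CTL replicate 3 (0.0141) or Runx1_FB_KO replicate 2 (0.00581), but had an adjusted p = 0.624 with an estimated correlation. With an estimated correlation and sex as a covariate 0 lists passed, with a smallest adjusted p = 0.67. Without Runx1_FB_KO replicate 3 the Wnt and growth factor lists passed (0.0114 and 0.0343). Without that library 0 lists passed with an estimated correlation, with a smallest adjusted p = 0.401. Without CTL replicate 1 the Wnt, skeletal muscle, epicardial and complement lists passed (0.0117, 0.0356, 0.00597 and 0.0132). Over all 6 libraries these had an adjusted p = 0.69, 0.618, 0.903 and 0.848 with an estimated correlation. Skeletal muscle also passed without Runx1_FB_KO replicate 2 (0.00581), and Schwann and neural without Runx1_FB_KO replicate 1 (0.0383), with the CPM filter (0.0334) and without mitochondrial genes and globins (0.0306), and both had an adjusted p = 0.618 with an estimated correlation over all 6 libraries. The matrix proteases and inhibitors list (adjusted p = 0.0604) held members in both directions: Mmp15 and Timp4 had log2 fold changes of 2.15 and 3.29 and were the 2 members past the threshold adjusted over the list alone, while the list median was -0.76. Among the RUNX factors and partners (0.13), Cbfa2t3 had 0.75 and Runx3 had -1.59 (-2.55 without Runx1_FB_KO replicate 3), and 0 members passed adjusted over the list alone. The endothelial list (0.468) had a median of -0.03 and a mean of 0.24, which differ in sign, and scores of 0.30, 0.29 and 0.10 in the knockout libraries. The resting fibroblast list (0.99) had a median of 0.10 (-0.36 with library size alone) and scores of 0.31, -0.01 and -0.06, while camera put it lower. The adipocyte list (0.781) had a median of -1.50 while camera put it higher, and the atrial list (0.934) a median of -0.39 and a mean of 0.24. The camera adjusted p was 0.958 for pericyte and smooth muscle, 0.0538 for dendritic cell, 0.0851 for neutrophil, 0.108 for Schwann and neural, 0.158 for skeletal muscle, 0.298 for resident macrophage and for lymphatic endothelial, 0.468 for erythroid, 0.618 for epicardial and mesothelial and for mast cell. It was 0.141 for Wnt signalling, for growth factors and angiogenesis and for secretory pathway stress, 0.178 for immediate early and heat shock, and 0.514 for complement.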

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

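The tests of endothelial against myofibroblast scores, of mitochondrial reads, of tissue mix, of depth, of Runx1_FB_KO replicate 3 and of Runx1 against fibroblast and macrophage lists were chosen after the results were seen. The counts over other splits of the samples were not.

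The genotype effect on 27 of the 41 lists differed between the sexes by camera with a preset correlation, which rests on 1 female control, 1 male knockout and 2 residual degrees of freedom. With an estimated correlation 0 lists differed (smallest adjusted p = 0.409), fry gave 0, and edgeR found 0 genes with a sex difference in the effect (276 at an unadjusted p under 0.05, smallest adjusted p = 0.463). The adjusted p of the difference was 2.44e-24 for adipocyte, 8.92e-23 for B and plasma cell, 1.84e-15 for erythroid, 3.97e-10 for epicardial and mesothelial, 1.43e-07 for dendritic cell, 4.57e-07 for Wnt signalling, 1.17e-05 for mast cell and 9.91e-05 for osteochondral and matrifibrocyte. It was 0.000154 for monocyte and for complement, 0.00017 for oxidative phosphorylation, 0.000233 for skeletal muscle, 0.000852 for fibrillar and structural matrix, 0.00129 for neutrophil, 0.00245 for lymphatic endothelial, 0.00586 for fetal and stress cardiomyocyte, and 0.00609 for myofibroblast and activated fibroblast and for proliferation. It was 0.0121 for mitochondrially encoded, 0.0133 for growth factors and angiogenesis, 0.0197 for TGF-beta signalling, 0.045 for cardiomyocyte, calcium handling, fatty acid oxidation and immediate early and heat shock, and 0.0464 for T and NK cell and for cytokines and chemokines. CTL replicate 1, the only female control, had an adipocyte score of -3.53 against 2.02 and 1.51 in the other controls. Runx1_FB_KO replicate 1 was the only male knockout, and Runx1_FB_KO replicate 3, which lay nearer CTL, was female. A sex difference in the effect therefore cannot be told apart from the spread between these libraries.

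Heart muscle and mitochondrial lists were higher while myofibroblast, matrix and macrophage lists were lower. If muscle RNA had only diluted every other cell type, endothelial and myofibroblast genes would have dropped alike, yet their score difference rose by 1.9 (SD 1.48 over the knockout libraries), with replicate 3 at 0.21 against at most 0.09 in CTL, although for resting fibroblast minus myofibroblast scores replicates 1 and 2 were at 2.52 and 2.68 but replicate 3 at 0.05, within CTL (-0.32 to 0.19). A larger share of mitochondrial reads lowers all nuclear genes alike. The cardiomyocyte score minus the mean of the myofibroblast, matrix and macrophage scores rose by 3.51 (SD 1.94), with every knockout library at 1.3 or more and CTL at most 0.22. These lists had already been seen to move apart, so that rise is no separate test. With mitochondrial genes and globins omitted, 19 called lists kept call and direction, all but the mitochondrially encoded list. Scaling and the comparison with other genes largely remove a shift shared by all nuclear genes. These calls could thus hardly have changed, and the fit does not test the mitochondrial share. A different mix of spared muscle and scar in the tissue taken cannot be told apart from genotype: with the cardiomyocyte score as a covariate 2 called lists kept call and direction, but that score was at least 1.14 in every knockout library and at most 0.20 in CTL. An effect of Runx1 loss on scar formation or muscle survival stays open and was not tested.

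Runx1_FB_KO replicate 3 lay nearer the controls than the other knockout libraries. A depth of 18201188 estimated reads, within the range of the other libraries, argues against low depth. If it were a control library like the others, splits with it in the place of a control would separate about as many genes as the real split, but the real split separated 5547 and those splits at most 2362 (SD 640 over 3 splits). This compares a few libraries whose genes move together. A control lying nearer the knockouts than the other controls could give the same order of counts, so a control library is not excluded. Weaker recombination, another infarct size or a partly mixed sample are not excluded either and were not tested.

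Runx1 was lower in every knockout library. Among 42 members of the myofibroblast and macrophage lists, 11.9% had a log2 fold change as low as that of Runx1, so part or all of its decrease may come from fewer such transcripts in the tissue. Relative to the mean of the myofibroblast and macrophage scores, Runx1 was -0.51, -0.95 and -0.21 in Runx1_FB_KO replicates 1, 2 and 3 and 0.00, 0.04 and -0.04 in CTL. Deletion in periostin-expressing cells stays open as well.

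The 6 samples allow 10 splits of 3 against 3, too few for a share under 0.05. For genes past the threshold the real split gave 0 and the highest other split 0, so 10 of 10 splits gave as many. For lists called the real split gave 20 and the highest other 26, and 4 of 10 splits gave as many. The 26 came with CTL replicate 1 and Runx1_FB_KO replicates 1 and 2 on a side. For separated genes the real split gave 5547 and the highest other 2362, and 1 of 10 splits, the real one, gave as many.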

How the results depend on the processing

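The fits with sample quality weights, DESeq2 on the filtered genes, and those with an estimated correlation that add sex or omit Runx1_FB_KO replicate 3, were chosen after seeing the data. The count of genes past the threshold was 0 in edgeR under sex as a covariate, RLE, upper quartile and library size scaling, CPM of at least 1 in 3 samples, an effective length offset, protein-coding genes, omission of mitochondrial genes, the cardiomyocyte covariate and glmTreat, and 0 in limma-voom. It was 889 in edgeR without a filter (850 higher, 39 lower, of 20211 tested) and 2311 at a threshold of 0.1. DESeq2, with its own default filter on mean counts, gave 2824 without filterByExpr (20191 genes with a p). On the genes that filterByExpr kept it gave 2995 (14227 with a p). Sample quality weights gave 8381 (4051 higher, 4330 lower), with Runx1_FB_KO replicate 3 at a weight of 0.145. Leaving out each library gave 0 to 6947 genes, and the 6947 came only without Runx1_FB_KO replicate 3. The lower spread then (a biological coefficient of variation of 0.232 against 0.322) accompanies that count; other causes were not tested. Runx1 was -2.61 to -1.07 over the left-out libraries, past the threshold only without Runx1_FB_KO replicate 3, and -2.35 with quality weights (adjusted p = 0.00015). Over all its alternatives the Runx1 adjusted p ran from 0.000142 to 0.846. The count of called lists was 16 to 23 over the left-out libraries and 16 to 22 over scalings, filters and covariates, though of the 19 with the cardiomyocyte covariate 12 were shared and 2 kept direction. It was 0 with an estimated correlation, with fry (smallest adjusted p = 0.161), with an estimated correlation and sex (0.67) and with an estimated correlation without Runx1_FB_KO replicate 3 (0.401). The first component held 68.9% of the variance over all genes in place of 56.5%. Library size alone moved the median log2 fold change of all genes to -0.52 from -0.06, and upper quartile to -0.13.

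Replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.051, 0.113 and 0.081. With the replicate block 0 genes passed, 22 lists were called, the glycolysis and hypoxia call was lost (0.0686), those of matrix proteases (0.044), dendritic cell (0.0267) and erythroid (0.0412) were gained, and Runx1 was -1.95. Without the block, camera with an estimated correlation gave these gained lists adjusted p of 0.618, 0.618 and 0.848. The block turned the sign of the uncalled adipocyte list (0.993).

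With the cardiomyocyte score as a covariate, which follows genotype, Runx1 and 32 of the other 72 named genes turned sign, and the cause was not tested. Runx1 was 1.197 and the other log2 fold changes were Cycs -0.043, Ndufb5 -0.17, Cox6a2 -0.085, Cpt1b -0.20, Etfdh -0.28, Hrc -0.12, Fap 0.62, Thbs2 0.77, Myl9 1.09, Fbln2 0.24, Col18a1 0.997, Col5a1 1.15, Crtap 0.37, Bmp1 0.70, Fkbp10 0.78, mt-Nd4l -0.23, Ccnb2 0.23, Aurka 0.20, Ccnb1 1.08, Tgfbi 0.36, Tgfb1 0.57, Ccr2 0.24, Runx2 0.64, Arg1 0.32, Cd63 0.37, Bst2 0.26, Ms4a1 0.10, Hk2 -0.041, Mmp15 -0.052, Timp4 -0.46, Cbfa2t3 -0.14, Runx3 0.79. In the same fit the resident macrophage list was called, with its direction kept (0.00187), and these lists turned, with adjusted p fibrillar and structural matrix 1.08e-12, myofibroblast and activated fibroblast 1.06e-14, collagen processing and crosslinking 1.43e-12, matrix proteases and inhibitors 0.00278, TGF-beta signalling 0.00526, osteochondral and matrifibrocyte 2.01e-05, RUNX factors and partners 0.142, calcium handling and excitation 0.67, oxidative phosphorylation 5.3e-07, fatty acid oxidation 2.17e-09, macrophage 5.57e-05, lipid-associated macrophage 0.00369, monocyte 0.142, dendritic cell 0.377, mast cell 0.904, endothelial 0.676, lymphatic endothelial 0.187, pericyte and smooth muscle 0.0233, epicardial and mesothelial 0.668, Schwann and neural 0.822, adipocyte 0.347, erythroid 0.0103, atrial 0.983, proliferation 1.74e-06, cytokines and chemokines 0.142, interferon response 0.526, secretory pathway stress 0.232, growth factors and angiogenesis 0.000828, Wnt signalling 0.00145, immediate early and heat shock 0.000506.

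Lists that were not called turned sign elsewhere, and the cause was not tested. Adjusted p with sex as a covariate was resting fibroblast 0.396, pericyte and smooth muscle 0.801, epicardial and mesothelial 0.612, complement 0.934. With library size alone it was resting fibroblast 0.867, mast cell 0.985, pericyte and smooth muscle 0.876, epicardial and mesothelial 0.893, erythroid 0.985. Without a filter it was resting fibroblast 0.967. With an estimated correlation and sex it was resting fibroblast 0.722, pericyte and smooth muscle 0.848, epicardial and mesothelial 0.848, complement 0.967. With an estimated correlation without Runx1_FB_KO replicate 3 it was resting fibroblast 0.981, atrial 0.971. Over all 6 left-out libraries, including those that kept the sign, it ran for resting fibroblast 0.399 to 0.939, pericyte and smooth muscle 0.614 to 0.953, epicardial and mesothelial 0.00597 to 0.905, complement 0.0132 to 0.72, adipocyte 0.0813 to 0.837, atrial 0.688 to 0.923, mast cell 0.23 to 0.942, erythroid 0.0865 to 0.974. Epicardial and mesothelial and complement turned, among these, only without CTL replicate 2 (0.496 and 0.72), and were called, with sign kept, without CTL replicate 1 (0.00597 and 0.0132).

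Of the values of the 72 named genes besides Runx1, 1266 kept direction and side of the threshold, 282 were newly past it and 32 turned direction. For lists, 702 values kept direction and side of the threshold. With direction kept, 107 lost and 28 gained the call. Another 62 turned direction, some of which also lost or gained a call, so these totals do not hold every call lost or gained. Depth was even, at 16598561 to 19987279 estimated reads. Simulated changes of 1 on the log2 scale were recovered in 7.5% of genes with this spread, changes of 2 in 65.7% and changes of 3 in 83.3%. Those draws were independent over libraries, while Runx1_FB_KO replicate 3 differed over many genes at once. In the real fit even Kcnip2 at 3.99 and Hrc at 3.96 did not pass, so these shares are not the power of the comparison. Leaving out a library moved 17 of the 73 named genes by over 1.5 times, 12 of them without Runx1_FB_KO replicate 3.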

Other observations

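The gene families, the genes seen in a single group and the genes near Runx1 were examined only after the main results were seen. Families defined by gene symbol were compared with the other genes by camera, adjusted over 18 families, and with an estimated correlation every adjusted p was at least 0.697. The mitochondrial ribosome (Mrpl and Mrps genes) had a median log2 fold change of 0.87, with 76 of 78 genes positive (adjusted p = 1.54e-15). Its scores were 0.97, 1.16 and 0.23 in Runx1_FB_KO replicates 1, 2 and 3, and its median was 0.34 to 0.91 under the other scalings. The mitochondrial translocases (Timm and Tomm genes) had a median of 0.72 over 23 genes (adjusted p = 3.42e-05), which was 0.19 to 0.76 under the other scalings. The cytosolic ribosome (Rpl and Rps genes) had a median of -0.43, with 73 of 74 genes negative (adjusted p = 2.55e-09), scores of -0.59, -0.39 and -0.22, and medians of -0.86 to -0.40 under the other scalings. Ribosomal protein genes share reads with pseudogenes, so single values are uncertain.

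Cathepsins had a median of -0.80 over 13 genes (adjusted p = 0.00789), Toll-like receptors -0.80 over 10 genes (0.0228) and integrins -0.70 over 25 genes (0.0093), negative under every scaling tried. Runx1_FB_KO replicate 3 hardly showed these: its integrin score was -0.01 (CTL -0.03 to 0.02), its cathepsin score -0.18 beside -1.24 and -1.12 in Runx1_FB_KO replicates 1 and 2, and its Toll-like receptor score -0.21 beside -0.88 and -1.08. Mitochondrial solute carriers (Slc25) had a median of 0.31 over 40 genes (0.0165) and the proteasome 0.19 over 49 genes (0.0403), but these were -0.18 and -0.31 with library size alone, where the median of all genes was -0.52. The proteasome score of Runx1_FB_KO replicate 3 was -0.07, below every CTL library (-0.05 to 0.11), beside 0.18 and 0.30 in replicates 1 and 2. Septins and unconventional myosins had a median of -0.41 over 30 genes (0.0405), or -0.84 with library size alone. Their score in Runx1_FB_KO replicate 3 was -0.03 (CTL -0.03 to 0.03), beside -0.44 and -0.67 in replicates 1 and 2. The other 9 families had an adjusted p of 0.09 or more.

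In 7 genes every library of a group had at most 2 reads and every library of the other group at least 10. Il12rb1, Crct1, Aipl1, Klri2 and Ces2c were seen in CTL, and Edn3 and Gm10108 in the knockout. Edn3, which encodes an endothelin, had 19, 10 and 17 reads in Runx1_FB_KO replicates 1, 2 and 3 and 1, 2 and 2 in CTL. Another split of the same samples gave 10 such genes, so their number does not set the genotypes apart. Gm10108, a processed pseudogene on chromosome 5 (13121448 to 13121766, GRCm38), had 29, 67 and 87 reads in the knockout and 0 in each CTL library. Its sequence matched Cycs over 319 bases with 2 mismatches, so its reads are uncertain.

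A hypothesis was that sequence linked to the conditional Runx1 allele alters neighbouring genes. Of 54 tested genes within 5 Mb of Runx1 on chromosome 16, 42.6% had all knockout values beyond all CTL values, against 38.9% of genes elsewhere (odds ratio 1.16, 95% confidence interval 0.65 to 2.06, two-sided Fisher's exact p = 0.579), so an excess was not detectable, and the interval leaves it open.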
